A study of Mus musculus with 3 samples.

How the data were processed

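Polyadenylated RNA was sequenced from 3 populations of C2C12 cells, a mouse myoblast line that fuses into myotubes when serum is lowered. Each population carried a lentivirus coding for a short hairpin RNA (shRNA), was kept under puromycin selection and was differentiated for 7 days in low horse serum, per the labels. 1 population expressed a control shRNA and 2 expressed different shRNAs against Tead4, called shRNA A and shRNA B here. Reads were single-end, from a library kit that does not mark the strand of origin, so reads of genes that overlap on opposite strands cannot be told apart.

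The authors' deposited table gave a raw read count per Ensembl gene and library, and a normalized value beside it. The submitters' processing notes name TopHat 1.0.12, Cufflinks 0.8.2, DESeq and the mm9 build, with no role or order. The program that counted reads, the annotation release and the treatment of reads that map to several genes were not given in the sources used here. The normalized values of the deposited table are a score with no unit of its own: each equalled the raw count multiplied by 1 factor per library and rounded. With factors of 1.00 for the control library, 0.801 for shRNA A and 1.02 for shRNA B, taken unrounded, 0 of the values differed from the rounded product. Tests used the raw counts. The table held 20162 genes, of which 1124 had 0 reads in all 3 libraries, and 87 symbols stood at more than 1 identifier. Of these identifiers, 18701 matched a GENCODE mouse gene list of a later build. That list served only for names and for which genes overlap, and no coordinates are given because its build is not the one the authors used.

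Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (14478) were scaled by the trimmed mean of M values (TMM), with factors of 0.979, 1.01 and 1.01 for the control, shRNA A and shRNA B libraries. The quasi-likelihood F test compared the 2 Tead4 shRNA libraries with the control library, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. This design leaves 1 residual degree of freedom. The spread comes from 2 libraries that carry different shRNAs, and the lone control library was assumed to vary like them. Nothing in the labels describes repeat cultures of 1 shRNA, so p-values measure only the spread between these libraries. The biological coefficient of variation was 16.4% and the prior degrees of freedom 20.9. Standard errors (SE) were computed as the absolute log2 fold change divided by the square root of F. CPM, the usual depth-scaled count, refers to the TMM-scaled library size.

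Each shRNA library was also set against the control library by the ratio of scaled counts, with a 95% exact (Clopper-Pearson) interval. Such a ratio compares 2 libraries and has no replicate check. Shares of reads carry intervals of the same kind. A library at 0 reads was set to a floor of 3 counts. Ratios against this floor are nominal values that lie above the lower limits of the exact intervals. Intervals and floors cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules. A gene counted as 2-fold changed in both libraries when both ratios were at least 2-fold in 1 direction with intervals that exclude no change. Because both ratios share the control library, 100 simulated sets of 3 unchanged libraries, drawn with the dispersions of the test, gave values for comparison. Those dispersions come from the spread between the 2 shRNA libraries. A control culture that differs by more than this spread, which would move both ratios together, was not simulated. Correlations across genes used log2 CPM with a prior count of 2.

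Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and, as an alternative, with an estimated correlation. In that alternative both the correlation and the test rest on 1 residual degree of freedom, so hardly any list could pass it. Its p-values therefore do not show whether correlation between genes accounts for a list, which stays unchecked. The function fry tested whether a list's genes moved, on balance, 1 way. Lists with at least 5 tested members entered, and p-values were adjusted over these 24 lists. For each shRNA library alone, the list's median log2 ratio was placed among 10000 random lists matched on mean expression. The lists, the design, the alternatives and the rule for named genes were fixed before the data were examined. That rule took Tead4 and its family first. It then took up to 15 genes in each direction that passed the test, changed at least 2-fold in both libraries and had a mean of at least 5 CPM, ranked by the smaller of the 2 log2 ratios. From each list it took the 4 called members with the highest CPM, or 2 members where none was called. Between the shRNAs it took 5 genes in each direction, and it added Tead4, Myog, Ddit3, Cdkn1a and Cav3 as known subjects of the study. Predicted genes were skipped. Genes named outside this rule were chosen after their values were seen and are marked as such.

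The test was tried on simulated counts for the same 14478 genes and comparison, with 200 genes changed in each of 20 draws. It recovered 42.8% of genes changed 2-fold and 83.6% of those changed 4-fold, and 6.59% of its calls were unchanged genes. With no gene changed it made 0.8 calls on average and at most 2. The simulated control library varied with the dispersions that the test itself assumes. These rates therefore do not check for calls caused by a lone control culture that differs for other reasons. Alternatives were median-ratio (RLE), upper-quartile and total-count scaling, no count filter, a mean count of at least 50, robust moderation, limma-voom, DESeq2 1.42.0, edgeR's likelihood-ratio test with a dispersion estimated over all 3 libraries as 1 group, and leaving out either shRNA library. The factors of the deposited normalized values, the newer quasi-likelihood method of edgeR, the same test with the dispersion over all 3 libraries, the likelihood-ratio test with the dispersion of the groups and leaving out genes at 0 in any library were added after seeing the data. Figures were drawn with matplotlib 3.10.9.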

Results

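The question was which genes depend on Tead4, a DNA-binding factor of the TEAD family, in differentiated C2C12 muscle cells. Transcript counts were available for 3 libraries of cells differentiated for 7 days: 1 control shRNA library and 2 Tead4 shRNA libraries, 1 for each shRNA. The control library held 16412139 counted reads, shRNA A 19918954 and shRNA B 15594305. The gene with the most reads, not corrected for transcript length, was Hspa5 in the control library (0.808% of reads, 95% exact interval 0.803 to 0.812). It was Fn1 with shRNA A (0.843%, 0.839 to 0.847) and Acta1 with shRNA B (0.651%, 0.647 to 0.655). The 14 mitochondrially encoded genes took 1.59% of reads in the control library (1.58 to 1.59), 2.09% with shRNA A (2.09 to 2.10) and 2.47% with shRNA B (2.46 to 2.48).

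Tead4 (ENSMUSG00000030353) was lower with both shRNAs. It had 1256 reads in the control library, 397 with shRNA A and 170 with shRNA B, or 78.2, 19.7 and 10.8 CPM. The log2 ratio to the control library was -1.99 with shRNA A (95% exact counting interval -2.15 to -1.82) and -2.86 with shRNA B (-3.10 to -2.63). Over both libraries the log2 fold change was -2.35 (SE 0.27, edgeR quasi-likelihood adjusted p = 2.82e-06). The other family members did not pass the test: Tead1 had a log2 fold change of 0.18 (SE 0.22), Tead2 of -0.60 (SE 0.23) and Tead3 of 0.21 (SE 0.25). The log2 ratios with shRNAs A and B were 0.10 and 0.25 for Tead1, -0.47 and -0.75 for Tead2, and 0.40 and -0.02 for Tead3. Both counting intervals for Tead2 excluded no change (-0.62 to -0.33 and -0.92 to -0.59). The interval for Tead3 with shRNA B included it (-0.21 to 0.17). Among 8 tested TEAD family members and cofactors, Tead4 fell and Vgll4, a transcription cofactor of TEAD proteins, rose (log2 fold change 0.96, SE 0.23). Adjusted over the list alone, 2 rose and 2 fell. The list did not pass the list test (camera adjusted p = 0.852), and its median of 0.19 differed in sign from its mean of -0.04 and from the test's direction.

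With Tead4 shRNA, many genes of the unfolded protein response, which is switched on by stress of the endoplasmic reticulum, fell, and many cell cycle genes rose. Hspa5, Ddit3 and Trib3 were among the first, and Plk1, Cdc20 and Ccnb2 among the second. In all, 773 genes rose and 649 fell, 9.82% of the 14478 tested, and 3143 genes had an unadjusted p under 0.05. At least 2-fold changes were found for 574 of the genes that rose and 380 of those that fell. DESeq2 called 444 genes higher and 368 lower. With the dispersion estimated over all 3 libraries as 1 group, edgeR's likelihood-ratio test called 0 genes in each direction (540 at an unadjusted p under 0.05). Neither choice alone did this: that test with the dispersion of the groups called 916 and 751 genes, and the quasi-likelihood test with the dispersion over all 3 libraries 753 and 616.

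The top-ranked genes that fell were led by Trib3, a pseudokinase induced by stress, at 262 CPM in the control library against 4.67 and 3.74 CPM with shRNAs A and B (log2 fold change -5.95, SE 0.25, adjusted p = 4.35e-13). Ddit3, which codes for the stress factor CHOP, fell by 4.75 on the log2 scale (SE 0.23). The glutathione-degrading enzyme Chac1 (-4.67, SE 0.23), the transcription factor Atf3 (-4.52, SE 0.25) and the reticulum protein Sdf2l1 (-4.30, SE 0.22) fell as well. The secreted factors Gdf15 (-4.86, SE 0.29) and Fgf21 (-3.95, SE 0.30) also fell. The reticulum chaperone Hspa5 (BiP) went from 132529 reads to 10314 and 9174 and fell by 3.91 (SE 0.24). The others were Herpud1, Creld2, the glycine transporter Slc6a9, the aminotransferase Bcat1, Cdsn, the calcium pump Atp2a3 and the slow myosin light chain Myl2, with log2 fold changes from -4.40 (Cdsn) to -3.20 (Myl2).

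The top-ranked genes that rose included Txnip, an inhibitor of thioredoxin induced by glucose, which went from 88 reads to 2074 and 1250 (log2 fold change 4.06, SE 0.30, adjusted p = 3.69e-09). The kinetochore gene Nuf2 rose by 3.69 (SE 0.43), the microtubule depolymerase Kif2c by 2.92 (SE 0.45), the mitotic kinase Plk1 by 2.84 (SE 0.43), Cdc20 by 2.73 (SE 0.35) and the centromere gene Cenpf by 2.66 (SE 0.29). Fignl1, Ccnb2, Kif20a, Cenpa and Pbk, also known from dividing cells, rose by 2.58 (Cenpa) to 3.26 (Fignl1). Prelp, a matrix proteoglycan, rose by 2.94 (SE 0.29), the alcohol dehydrogenase Adh1 by 2.98 (SE 0.40) and Trib2 by 2.81 (SE 0.40). Trp53i13 headed the ranking with 0 reads in the control library against 324 with shRNA A and 219 with shRNA B. Against the floor of 3 counts it was nominally 6.43 and 6.22 higher on the log2 scale, with exact lower limits of 6.12 and 5.91. It belongs to a set of genes that were at 0 in 1 library and abundant in another, and it overlaps the gene Abhd15, so its value is uncertain.

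**Figure D1:**
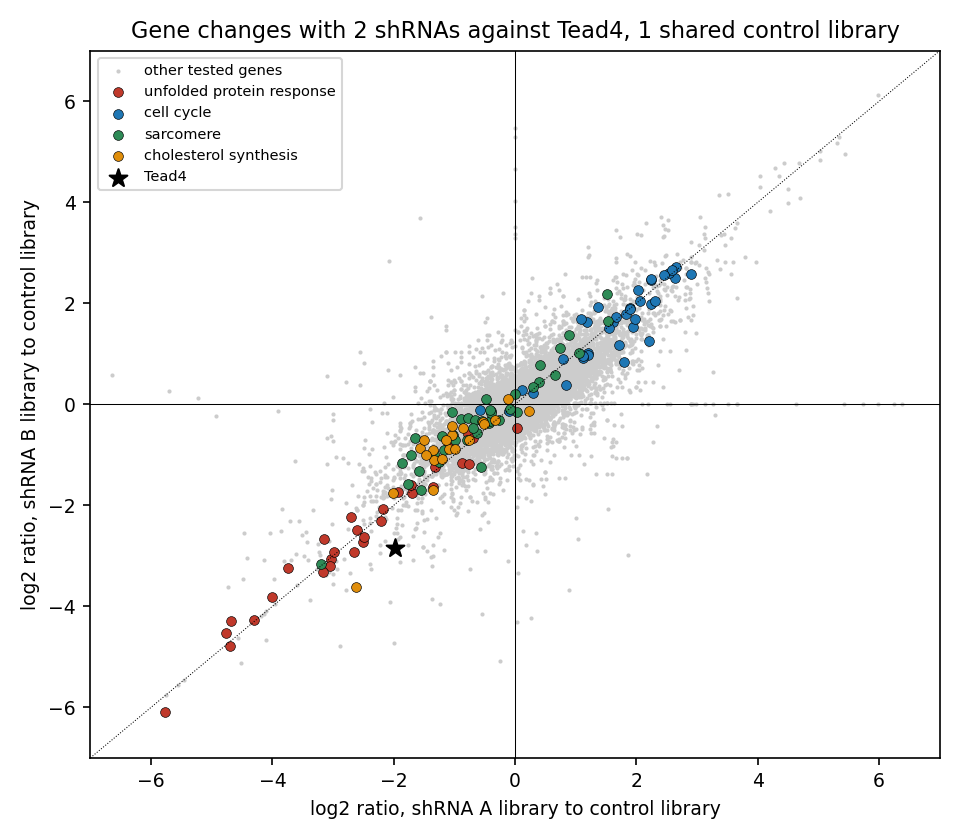
Each point is 1 of 14478 tested genes, with the log2 ratio of the shRNA A library to the control library on the horizontal axis and of the shRNA B library to the control library on the vertical axis (prior count of 2), and colours mark 4 gene lists and Tead4. Unfolded protein response genes lie at the lower left and cell cycle genes at the upper right, along the dotted line of equal ratios. Both axes share the control library, which alone gives a correlation (0.508 in simulated unchanged libraries).

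Of 30 tested genes of the unfolded protein response, 27 fell and 0 rose, with a median log2 fold change of -2.56. Besides Hspa5, the chaperones Hsp90b1 (-3.05, SE 0.24) and Calr (-1.83, SE 0.24) and the disulfide isomerase Pdia3 (-1.65, SE 0.23) fell. So did the transcription factors Atf4 (-2.55, SE 0.23) and Xbp1 (-1.29, SE 0.22). The 3 members not called were Canx (-0.68, SE 0.24), Atf6 (-0.67, SE 0.23) and Eif2ak3 (-0.20, SE 0.25; 0.03 with shRNA A and -0.48 with shRNA B); these 5 genes were chosen after their values were seen. Adjusted over the list alone, 29 fell. The list's median log2 ratio was -2.56 with each shRNA, below all 10000 matched random lists (percentile 0 in both). The list test (camera) gave an adjusted p of 8.53e-150, which became an adjusted p = 0.508 with an estimated correlation, and fry, which tests whether genes of a list moved 1 way on balance, gave an adjusted p of 0.0492. For every other list fry gave 0.240 (cell cycle) to 0.837. Because Ddit3 and this response are known subjects of the study, the list is not independent evidence of its direction.

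Of 36 tested cell cycle genes, 29 rose and 0 fell, with a median log2 fold change of 1.76. The ribonucleotide reductase subunit Rrm2 rose by 0.84 (SE 0.23), cyclin D1 (Ccnd1) by 2.16 (SE 0.25), topoisomerase Top2a by 1.91 (SE 0.25) and the replication helicase subunit Mcm6 by 1.02 (SE 0.25). The proliferation marker Mki67, named after its value was seen, rose by 2.59 (SE 0.28), while Pcna (0.20, SE 0.24; 0.11 with shRNA A and 0.28 with shRNA B) and Mcm7 (-0.12, SE 0.24), likewise, were not called. Adjusted over the list alone, 30 rose. With camera the adjusted p was 9.45e-30, and adjusted p = 0.567 with an estimated correlation; fry gave 0.240.

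Inhibitors of the cell cycle did not pass the list test (13 tested, 1 rose and 3 fell, also when adjusted over the list alone; camera adjusted p = 0.164). Gadd45a (-1.47, SE 0.23), the kinase inhibitor Cdkn1b (-0.72, SE 0.21) and Btg1 (-0.71, SE 0.23) fell, and Gadd45g rose by 0.84 (SE 0.24). Cdkn1a, which codes for the kinase inhibitor p21, was not called at a log2 fold change of -0.40 (SE 0.25, adjusted p = 0.388), or -0.58 with shRNA A and -0.23 with shRNA B. Of 18 p53 target genes, 6 fell and 3 rose (7 and 3 when adjusted over the list alone), with a median of -0.31. The median log2 ratio was -0.45 with shRNA A (percentile 0.09 of matched random lists) and -0.18 with shRNA B (percentile 4.05, inside their central 95%). Plk2 (-1.61, SE 0.22), Pmaip1 (-0.95, SE 0.24), Eda2r (-0.85, SE 0.26) and the ubiquitin ligase Mdm2 (-0.82, SE 0.22) fell. Those that rose, named after their values were seen, were Perp, Zmat3 and Ckap2 (2.85, 0.82 and 1.81). Eda2r had a log2 ratio of -0.53 with shRNA B alone. Camera gave p53 targets an adjusted p of 0.00614, and adjusted p = 0.654 with an estimated correlation. Another scaling and DESeq2 each ended the calls of Btg1, Cdkn1b and Eda2r. The calls of Gadd45g, Pmaip1, Zmat3 and Perp also ended with DESeq2, and that of Perp with limma-voom.

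**Figure D2:**
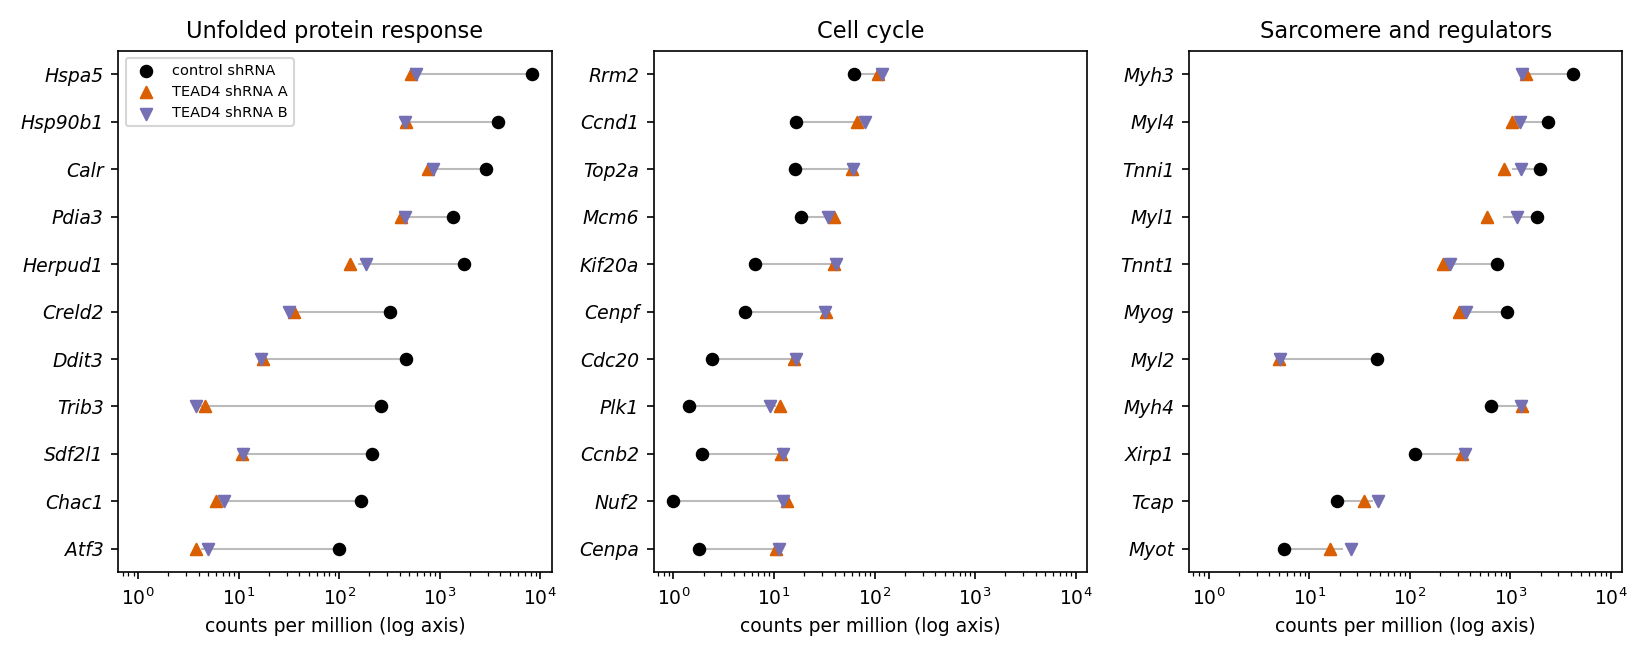
CPM on a log axis for 11 genes of each of 3 groups, with circles for the control library, upward triangles for shRNA A and downward triangles for shRNA B; grey lines join the control value to the mean of the shRNA libraries. The stress genes lie to the left of the control with both shRNAs, the cell cycle genes to the right, and Myh4, Xirp1, Tcap and Myot go against the other genes of the muscle panel.

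Myogenin (Myog), a muscle regulatory factor that acts in differentiation, fell from 914 CPM to 308 and 365 CPM (log2 fold change -1.44, SE 0.24, adjusted p = 2.73e-04), and Myf5, a related factor, fell by 1.35 (SE 0.24). Myod1 was not called (0.71, SE 0.23, adjusted p = 0.0570, named after its value was seen). The 14 myogenic regulatory factors did not pass the list test (0 rose, 2 fell, or 1 and 3 adjusted over the list alone; camera adjusted p = 0.364), and their median of 0.11 differed in sign from their mean of -0.13 and the test's direction; the median log2 ratio was -0.11 with shRNA A and 0.21 with shRNA B.

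Sarcomere genes, which build the contractile apparatus, changed in both directions: 15 of 41 fell and 5 rose, with a median of -0.48. The embryonic myosin heavy chain Myh3 fell by 1.63 (SE 0.24), as did the light chains Myl1 (-1.08, SE 0.29) and Myl4 (-1.04, SE 0.24) and the slow troponin subunit Tnni1 (-0.89, SE 0.26). Those that rose, named after their values were seen, were Myot (1.90, SE 0.33), Xirp1 (1.60, SE 0.25), Tcap (1.15, SE 0.26), the fast myosin heavy chain Myh4 (1.03, SE 0.25) and the small heat shock protein Cryab (0.94, SE 0.26). Adjusted over the list alone, 17 fell and 7 rose. The list's median log2 ratio was -0.57 with shRNA A and -0.32 with shRNA B, and Myl1 had -1.66 and -0.67. By camera, the list had an adjusted p of 6.44e-06, and adjusted p = 0.654 with an estimated correlation. The calls of Tnni1 and Myl1 ended under RLE scaling, that of Tnni1 also under upper-quartile scaling and that of Myl1 also with DESeq2.

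Of 21 genes of excitation-contraction coupling, 9 fell and 0 rose, with a median of -0.61. The calcium pump Atp2a2 fell by 1.37 (SE 0.24), as did the calcium release channel Ryr1 (-0.83, SE 0.24) and the calcium channel subunits Cacnb1 (-0.79, SE 0.23) and Cacna1s (-0.74, SE 0.23). Camera gave an adjusted p of 6.44e-06, and adjusted p = 0.654 with an estimated correlation. Adjusted over the list alone, 11 fell and 1 rose, and another scaling ended the calls of Cacnb1 and Cacna1s.

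Neuromuscular junction genes did not pass the list test (13 tested, camera adjusted p = 0.364): the fetal acetylcholine receptor subunit Chrng fell by 0.90 (SE 0.25) and Dok7 rose by 0.84 (SE 0.24), and adjusted over the list alone 3 fell and 1 rose. Of 18 genes of myoblast fusion and adhesion, Gm7325, which codes for a micropeptide needed for fusion, fell by 1.60 (SE 0.23) and the cadherin Cdh15 fell by 0.75 (SE 0.23); adjusted over the list alone 3 fell and 1 rose (camera adjusted p = 0.379). Cav3, a caveolin of muscle, was not called at -0.66 (SE 0.22, adjusted p = 0.0600). Of 16 genes of the dystrophin complex, dystrophin (Dmd) fell by 1.77 (SE 0.22) and the laminin chain Lama2 fell by 0.79 (SE 0.23), also when adjusted over the list alone (camera adjusted p = 0.204). Upper-quartile scaling ended the calls of Cdh15 and Lama2, and DESeq2 those of Lama2 and Dok7.

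Smooth muscle markers rose in 5 of 11 tested members, with a median of 1.12 and none lower (6 adjusted over the list alone). Smooth muscle actins Actg2 and Acta2 rose by 2.50 (SE 0.31) and 1.09 (SE 0.27), the actin-binding proteins Tagln and Cnn2 by 1.58 (SE 0.26) and 1.12 (SE 0.26), and Lmod1, named after its value was seen, by 2.07 (SE 0.37). The list test (camera) gave an adjusted p of 6.01e-06, and adjusted p = 0.654 with an estimated correlation. The newer quasi-likelihood method ended the call of Acta2.

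Of 41 extracellular matrix genes, 10 rose and 2 fell, with a median of 0.57. The proteases Mmp14 and Mmp2 rose by 1.46 (SE 0.29) and 1.07 (SE 0.29) and Thbs1 by 1.34 (SE 0.31), while the proteoglycan Dcn fell by 0.91 (SE 0.23), as did Postn (-0.94, SE 0.22), named after its value was seen. Adjusted over the list alone, 19 rose and 2 fell. The list's median log2 ratio was 0.81 with shRNA A and 0.18 with shRNA B. With camera the adjusted p was 4.34e-05, and adjusted p = 0.654 with an estimated correlation. With shRNA B alone the log2 ratio was 0.83 for Thbs1 and 0.65 for Mmp2. DESeq2 ended the call of Thbs1.

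Genes known as targets of YAP and TEAD factors rose in 6 of 23 tested members, with a median of 0.41 and none lower (9 higher and 1 lower adjusted over the list alone). Cyr61, a secreted matrix protein, rose by 1.65 (SE 0.26), the growth factor Tgfb2 by 1.11 (SE 0.23), the phosphatase Ptpn14 by 1.01 (SE 0.27) and Asap1 by 0.87 (SE 0.26); with shRNA B alone Ptpn14 and Asap1 had log2 ratios of 0.59 and 0.56. By camera, the list had an adjusted p of 1.99e-04, and adjusted p = 0.654 with an estimated correlation. Genes of satellite and reserve cells, the undifferentiated cells of muscle, rose in 6 of 15 members (9 adjusted over the list alone), with a median of 0.69. The Fgf signalling inhibitor Spry1 rose by 1.18 (SE 0.26), the syndecan Sdc3 by 1.16 (SE 0.25), Id1 by 1.08 (SE 0.26) and the Notch target Hes1 by 0.80 (SE 0.25). Camera gave an adjusted p of 5.01e-05, and adjusted p = 0.654 with an estimated correlation. RLE scaling ended the calls of Asap1 and Hes1, DESeq2 those of Hes1 and Id1, and limma-voom that of Hes1.

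In the insulin-like growth factor axis, Igf1 rose by 1.30 (SE 0.25), the adaptor Irs1 by 1.22 (SE 0.25) and the binding protein Igfbp4 by 0.95 (SE 0.26), 3 of 14 members (5 adjusted over the list alone) with a median of 0.36. The list test (camera) gave an adjusted p of 0.0133, and adjusted p = 0.654 with an estimated correlation. DESeq2 ended the call of Igfbp4.

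Genes of cholesterol synthesis and its control fell in 14 of 21 tested members and rose in 0, with a median of -0.94 (16 lower adjusted over the list alone). The enzymes Sc4mol (-1.22, SE 0.23), Cyp51 (-0.80, SE 0.24) and squalene epoxidase (Sqle, -0.73, SE 0.22) fell, as did the feedback regulator Insig1 (-1.05, SE 0.26). With camera the adjusted p was 8.27e-16, and adjusted p = 0.654 with an estimated correlation. RLE and upper-quartile scaling ended the calls of Cyp51 and Sqle.

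Glycolysis and creatine kinase genes did not pass the list test (24 tested, 3 fell, camera adjusted p = 0.0527; 4 fell and 1 rose adjusted over the list alone). The list's median log2 ratio was -0.40 with shRNA A and -0.0008 with shRNA B. Those that fell were hexokinase Hk2 (-2.02, SE 0.22), muscle creatine kinase Ckm (-1.06, SE 0.24) and the glucose transporter Slc2a1 (-0.96, SE 0.21). Among 33 nuclear genes of the respiratory chain and related proteins, myoglobin (Mb) fell by 1.85 (SE 0.28) and Cox7a1 fell by 1.41 (SE 0.42), 1 gene when adjusted over the list alone. That list did not pass the list test (camera adjusted p = 0.431), and its median of -0.02 changed sign with total-count and upper-quartile scaling. Its median log2 ratio was -0.15 with shRNA A and 0.17 with shRNA B, in opposite directions. The share of reads on mitochondrially encoded genes was 1.59%, 2.09% and 2.47% in the control, shRNA A and shRNA B libraries. Of 18 genes of muscle atrophy and growth, the autophagy receptor Sqstm1 (-0.99, SE 0.24), the ubiquitin ligase Trim63 (-1.27, SE 0.24) and Bnip3 (-0.76, SE 0.23) fell, with 4 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.164). RLE scaling ended the calls of Cox7a1 and Bnip3, and DESeq2 those of Cox7a1, Bnip3 and Mb.

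Inflammatory signalling genes fell in 5 of 15 tested members and rose in 0, with a median of -0.43 (6 lower and 3 higher adjusted over the list alone), or -0.65 with shRNA A and -0.57 with shRNA B. Those that fell were the prostaglandin synthase Ptgs2 (-2.74, SE 0.22), Tlr2 (-1.78, SE 0.23), Nfkb2 (-0.84, SE 0.22), Tnfaip3 (-0.79, SE 0.22) and the chemokine Cxcl5 (-1.15, SE 0.34), the last named after its value was seen. By camera, the list had an adjusted p of 0.00277, and adjusted p = 0.654 with an estimated correlation. Of 20 interferon response genes, Ifih1 (7, 56 and 35 reads), Bst2 and Eif2ak2 rose by 2.51 (SE 0.74), 1.66 (SE 0.30) and 0.84 (SE 0.25), with 5 higher adjusted over the list alone and a median of 0.45. The median log2 ratio was 0.58 with shRNA A (percentile 99.87) and 0.26 with shRNA B (percentile 94.9, inside the central 95% of random lists). Camera gave an adjusted p of 0.0388, and adjusted p = 0.654 with an estimated correlation. DESeq2 ended the calls of Tnfaip3, Cxcl5, Ifih1 and Eif2ak2, and the interferon list was no longer past the threshold with a mean count of at least 50.

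Immediate early genes changed in both directions and did not pass the list test (19 tested, camera adjusted p = 0.379; 4 and 4 adjusted over the list alone). Egr1 and Egr3, transcription factors induced by growth signals, rose by 1.67 (SE 0.24) and 1.57 (SE 0.27), as did Egr2 (2.10, SE 0.37). Klf4 (-2.21, SE 0.21), Myc (-1.92, SE 0.22) and Ier3 (-0.86, SE 0.24) fell. Egr2 and Ier3 were named after their values were seen, and DESeq2 ended the call of Ier3.

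Markers of other lineages were sparse. Of 8 tested osteoblast and cartilage markers, Dmp1 (8, 59 and 64 reads) and Phex rose by 2.79 (SE 0.66) and 2.43 (SE 0.35), also when adjusted over the list alone, with a median of 0.55. The median log2 ratio was 0.21 with shRNA A (percentile 74.12, inside the central 95% of random lists) and 0.74 with shRNA B (percentile 99.45). The list had a camera adjusted p of 0.0399 and adjusted p = 0.654 with an estimated correlation. The adipocyte list had 4 tested members, of which Cebpa rose by 1.17 (SE 0.27), also adjusted over the list alone, and was too short for the list test. So was the leukocyte and endothelial list, with 4 tested members and none called, also adjusted over the list alone: Cd68 had 22, 45 and 44 reads and Vwf 9, 19 and 15. The osteoblast list was no longer past the threshold with a mean count of at least 50, and DESeq2 ended the call of Dmp1.

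**Figure D3:**
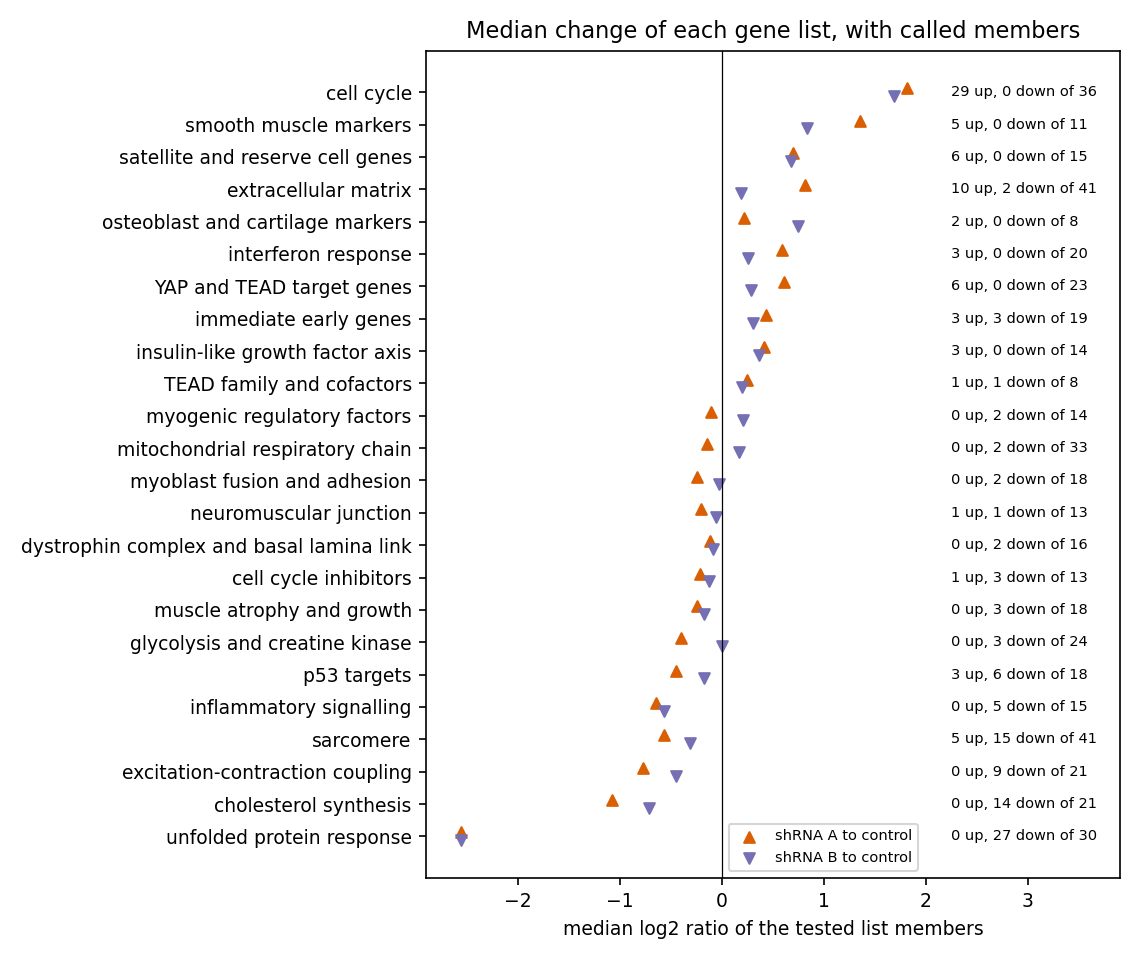
Median log2 ratio of each tested gene list to the control library, with upward triangles for shRNA A and downward triangles for shRNA B, and the number of members called higher and lower at the right. The unfolded protein response lies at -2.56 with both shRNAs and cell cycle genes at 1.82 and 1.69; extracellular matrix genes lie at 0.81 and 0.18.

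Many of the same genes differed from the control library by at least 2-fold with both shRNAs. With shRNA A 1258 genes were higher and 852 lower than in the control library, and with shRNA B 928 and 685. Both libraries shared 669 higher genes, against 87.0 in simulated unchanged libraries and 80.6 for independent lists, and 449 lower genes, against 68.2 and 40.3. Of these, 428 and 308 also passed the test. In opposite directions, 3 genes were higher with shRNA A and lower with shRNA B, and 1 gene the reverse, all of them known only by clone names. The log2 ratios of the 2 libraries correlated across genes with r = 0.766, against 0.508 in simulated unchanged libraries (range 0.487 to 0.530); their covariance was 0.472 against 0.106, a difference of 0.366, and 77.5% of genes had the same sign against 66.8%. Genes are not independent replicates. The control library cannot be split, and the simulation gives it only the spread seen between the shRNA libraries. Part or all of the excess may therefore come from the shared control.

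Between the 2 shRNA libraries, 313 genes were at least 2-fold higher with shRNA A and 326 with shRNA B; no count expected by chance is set beside these, because the spread in the test comes from the same 2 libraries. The collagen gene Col16a1 was higher with shRNA A by 1.34 on the log2 scale (95% exact counting interval 1.0 to 1.70), Car9, a carbonic anhydrase, by 1.32 (0.84 to 1.82) and Fbxo46 by 1.31 (0.92 to 1.72). The mitochondrially encoded mt-Nd3 had a log2 ratio of shRNA A to shRNA B of -1.73 (-1.79 to -1.66), Serpinb7 of -1.62 (-1.78 to -1.45), Mcpt8 of -1.60 (-2.06 to -1.15), Zmynd17 of -1.42 (-1.58 to -1.26) and Tceal7 of -1.36 (-1.49 to -1.23). Rcl1 had 0, 442 and 0 reads in the control, shRNA A and shRNA B libraries, and Wdr92 265, 349 and 0. Against the floor of 3 counts they were 6.85 and 6.51 higher with shRNA A than with shRNA B (95% exact lower limits 6.55 and 6.20). Both belong to the genes at 0 in 1 library whose counts are uncertain. With 1 library for each shRNA, these ratios compare libraries and have no test between the shRNAs.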

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

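The tests of the single control library, of the share of differentiated cells and of a switch by Tead4 shRNA were chosen only after the result was seen. Among the genes that the naming rule took, 4 drew attention because their ratio to the control library went opposite ways with the 2 shRNAs, each with a counting interval that excludes no change. Over all tested genes 458 of 14478 met this criterion, so these 4, all of them named for differing between the shRNAs, are not exceptional in it; the difference between the shRNAs was not tested, as each has 1 library. Fbxo46 was 1.31 higher with shRNA A than with shRNA B on the log2 scale. The log2 ratio of shRNA A to shRNA B was -1.73 for mt-Nd3, -1.42 for Zmynd17 and -1.36 for Tceal7.

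The fall of unfolded protein response genes with both shRNAs was weighed first. A few abundant genes shifting the scaling is argued against: with the list and the 100 most abundant genes left out of the scaling factors, the list's median log2 fold change was -2.57. A glucose-poor control culture, which could raise this response and lower Txnip, was to be tested by Arrdc4, a gene with the same glucose response, but Arrdc4 had 6 reads over the 3 libraries and the test decides nothing. A state of the control culture that does not depend on Tead4 and an effect of Tead4 cannot be told apart, because there is 1 control library and the high level lies in it alone. A dependence on Tead4 therefore stays open as a hypothesis.

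The rise of cell cycle genes with the fall of sarcomere genes was weighed next. A lower share of differentiated cells in the shRNA cultures would lower all transcripts of differentiated muscle by about the same factor. Of the sarcomere genes, 10 that other cells or early stages may express were left out, though the embryonic Myh3, which fell, was kept. Among the remaining 31, 14 fell while 4 (Myh4, Myot, Tcap and Xirp1) rose by at least 2-fold. These 4 were also called under RLE, total-count and upper-quartile scaling. That argues against a lower share as the whole account of the muscle genes, and more undifferentiated cells beside a change within myotubes stays open for the cell cycle genes. A direct effect of Tead4 was not tested. Such an effect and the argument from the 4 genes that rose share the limit of 1 control library.

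The third pattern was 35 genes at 0 reads in 1 library or more and at least 50 reads in another, among them Trp53i13, Rcl1, Wdr92, Cntf (0, 192 and 0 reads), Fgf2 (0, 90 and 64) and Entpd2 (80, 0 and 0), of which the last 3 were picked after their values were seen. A switch by Tead4 shRNA is argued against as the account of the whole set. Both shRNAs lowered Tead4, yet 57.1% of the genes (20 genes) were at 0 in only 1 of the 2 shRNA libraries. Of the 20, 10 were also at 0 in the control library, which leaves 28.6% with the 0 in 1 shRNA library and nowhere else. The other genes have the pattern of a shared switch: 11 were at 0 in the control library alone and 4 in both shRNA libraries. For those a switch stays open. Reads counted to an overlapping gene instead is a candidate explanation: 79.2% of the 24 genes that could be placed overlap another gene, against a median of 25% in matched random sets, of which the central 95% reached up to 45.8%. That check is void as a test because only 68.6% of the 35 genes could be placed, so it remains open. Of the 35 genes, 23 were called, 19 of them higher. Some called higher, such as Rcl1 (edgeR quasi-likelihood adjusted p = 0.0121) and Cntf, had reads with shRNA A only. The test can therefore call genes on which the 2 shRNAs disagree, and such calls are among the 773 genes that rose.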

How the results depend on the processing

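The deposited factors, the newer quasi-likelihood method, leaving out genes at 0 in any library, the likelihood-ratio test with the dispersion of the groups and the quasi-likelihood test with the dispersion over all 3 libraries were chosen after seeing the data. The numbers of genes called higher and lower stayed within 1.5 times of 773 and 649 under RLE (626 and 562), total-count (911 and 599) and upper-quartile scaling (746 and 516), no filter (1020 and 779), a mean count of at least 50 (834 and 728), deposited factors (675 and 581), robust moderation (755 and 648), the newer method (796 and 683), limma-voom (689 and 679), the likelihood-ratio test with the dispersion of the groups (916 and 751), the quasi-likelihood test with the dispersion over all 3 libraries (753 and 616) and without genes at 0 (905 and 763). DESeq2 gave 444 and 368 (2070 genes at an unadjusted p under 0.05). The likelihood-ratio test with the dispersion over all 3 libraries gave 0 and 0 (540 unadjusted) and Tead4 a log2 fold change of -2.36 with an adjusted p of 0.885, where the 14 alternatives ranged from 3.02e-20 to 0.885; its coefficient of variation of 27.6% counts the difference between the groups as spread. Tead4 was lower in all of these, and from -2.86 to -1.99 with 1 shRNA library left out. Genes 2-fold changed in both libraries numbered 399 higher and 273 lower with a mean count of at least 50. At 1.5-fold the genes changed in both numbered 1301 and 1018, and at 3-fold 300 and 206. With 1 shRNA library left out, the remaining library alone gave 928 to 1258 higher and 685 to 852 lower. Those counts do not require a change in both libraries. Between the shRNAs, 61 and 73 genes were 2-fold apart with a mean count of at least 50, so most such genes had few reads. The correlation of the 2 shRNAs was 0.694 with no filter and 0.828 with a mean count of at least 50. Of 8 lists higher and 6 lower, 0 and 0 remained past the threshold with an estimated correlation, the glycolysis list passed it with no filter and with a mean count of at least 50 but had a median of -0.40 with shRNA A and -0.0008 with shRNA B, and the respiratory chain, not past it, changed sign with total counts (0.0263) and upper-quartile scaling (0.0199). The uncalled gene Fbxo46 changed sign with limma-voom (-0.0792). Where not explained above, the cause was not tested. Of 146 named and called genes, RLE scaling ended 16 calls, total counts 3, upper-quartile scaling 16, deposited factors 10, robust moderation 6, the newer method 3, limma-voom 6, DESeq2 25, the quasi-likelihood test with the dispersion over all 3 libraries 3 and the likelihood-ratio test with it all 146. No paired analysis was possible because there is 1 control library and no pairing of cultures is described. Depth limits genes near the floor of 3 counts, which is 0.187, 0.149 and 0.190 CPM in the control, shRNA A and shRNA B libraries.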

Other observations

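All lists in this part were chosen after the data were seen, so their p-values describe the lists and are not independent tests. Of 20 cytosolic aminoacyl-tRNA synthetases, 13 fell, 0 rose and 7 were not called, with a median log2 fold change of -1.15, and Wars, the tryptophan enzyme, fell by 1.84 (SE 0.21). Of 17 genes of amino acid synthesis and transport, 14 fell and 0 rose, while Pycr1, Slc7a11 and Cbs were not called, with a median of -1.29. The amino acid transporter Slc7a5 (-2.20, SE 0.23) and the serine synthesis enzyme Psph (-2.13, SE 0.23) fell. So did the cysteine synthesis enzyme Cth (-4.34, SE 0.47), with 197, 7 and 14 reads in the control, shRNA A and shRNA B libraries. Camera gave adjusted p-values of 3.35e-18 and 5.84e-30, and adjusted p = 0.111 for both with an estimated correlation.

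Of 36 genes of the translocon and vesicle coat of the secretory pathway, 5 fell, with a median of -0.25, namely Rpn1 (-1.01), Spcs2 (-0.92), Ostc (-0.88), Spcs3 (-0.76) and Ssr2 (-0.76), and 31 were not called; upper-quartile scaling ended the call of Spcs3. Camera gave an adjusted p of 0.00197, and adjusted p = 0.397 with an estimated correlation. Of 13 mitochondrially encoded genes, mt-Nd5 and mt-Nd6 rose by 0.84 (SE 0.25) and 0.83 (SE 0.25), and the median was 0.56. Log2 fold changes of mt-Nd3 (-0.35, SE 0.38) and mt-Atp8 (-0.40, SE 0.30) were negative and not called. For this list camera gave an adjusted p = 0.00564, and adjusted p = 0.513 with an estimated correlation. RLE scaling and deposited factors each ended both calls, and robust moderation and the newer quasi-likelihood method that of mt-Nd5.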
